A study of Mus musculus with 3 samples.

How the data were processed

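RNA of HoxA9-Meis1 AML cells was hybridized to 3 one-colour arrays: 1 of untreated cells, 1 of cells given 3.4 µM Pyrydopyrazine A2 and 1 of cells given retinoic acid and 1α-hydroxy vitamin D3 at 10 µM each, all for 24 h. Per the labels, 50 ng of total RNA treated with DNase was labelled with Cy3. The deposited scanner files hold spot intensity from Agilent Feature Extraction 11.5.1.1 for a mouse array with probe positions in genome build mm9. Per the file headers, the processed signal is an intensity corrected for background and spatial trend, with no scaling between arrays. The deposited flags, values of 0 or 1 set by the authors' scanner software, mark spots that are well above background, saturated or uneven. The authors' deposited value table is an intensity on a linear scale. Its columns had been quantile normalized, since 99.9% of sorted values were equal in the 3 columns within 0.01%.

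The labels of the treated arrays differ between the sources. By rank over all spots each treated column of the value table equals the scanner file with the other treated label. The scanner files' labels were used, and which source is right was not decided. The value table's control column matched no scanner file and served as a second control in the comparisons that name it.

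Control spots and 25 probes marked as uneven were left out, which left 55681 probes. The log2 processed signal minus the log2 of the array's 75th percentile was used, and spots of one probe were averaged. Probes were given gene names by transcript accession (27656), symbol (3401) or synonym (321) from a RefSeq table of mouse genes, and 24303 kept the name in the scanner file. Of 34769 names 22365 were in the RefSeq table. The reference annotation is of a later build than the probe positions, so exons and untranslated regions are not given. For the 11169 genes with more than 1 probe, the probe with the highest mean log2 signal over the 3 arrays was used. A gene or transcript was measured in a comparison when its probe was well above background on both arrays, and was counted as higher or lower at a difference of at least 2-fold.

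Where a gene's probe was well above background on 1 of the arrays and no probe of the gene was on the other, its fold is a bound. It was computed as the ratio of its signal to the larger of the probe's signal on the other array and the lowest signal of any probe well above background there, and is written as "at least". Genes below background on both arrays have no fold.

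The comparisons were each treated array against the untreated array, and the treated arrays against each other. With 1 array per condition no test across samples was run. Precision was judged from the replicate spots within arrays and from the difference between the control sources. For each of 33 lists (26 gene lists and 7 lists of cell type markers) with at least 4 measured members, the median log2 difference was set against 10000 random lists of the same size drawn from genes in the same of 10 bins of mean signal. The percentile is the share of random medians below it and describes these arrays alone. The range of 95% runs from percentile 2.5 to 97.5.

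The lists, the comparisons and the rule for named genes were set before the data were examined. The rule took, among genes in the RefSeq table (predicted genes, clones, receptor segments and olfactory receptors excepted) whose brighter signal lay above the array's median of detected probes, the 12 largest increases and 12 largest decreases of each treated array and the 8 largest each way between the treated arrays. It added the 4 largest bounds each way, up to 3 of the highest and 3 of the lowest members of each list, and 12 genes named whatever their value: Hoxa9, Meis1, Rarb, Cyp26a1, Cyp24a1, Vdr, Cd14, Itgam, Csf1r, Cdkn1a, Myc and Kit. A pair of genes that the rule takes is not reported here. Other genes named with a value were chosen after their values were seen.

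The similarity of both differences was computed as Pearson's r, Spearman's rho and the covariance over genes measured on all 3 arrays. To show what the shared control array gives, 100 sets of 3 arrays without effects were simulated with normal noise set by the SD between the control sources. Runs of alternating G and T of at least 8 bases were searched in the 60-base probe sequences after such probes had been noticed among the largest decreases.

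The steps were tested on simulated data with a noise SD of 0.203 on the log2 scale. Of 50 genes each given a log2 change of 1.5 or -1.5, 92.0% and 98.0% were called, and of 50 given 3 or -3, 100% and 100%. Of 17079 unchanged genes 0.0703% were called. The simulated noise was normal with the same SD for every gene, so this share is not the rate of false calls on the real arrays. Between the 2 control sources 0.935% of 17003 genes lay at least 2-fold apart.

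The alternatives set before the data were examined were background correction by normexp with an offset of 50, scaling to the median of detected probes, quantile normalization, the value table with its columns as labelled, the mean over all probes of a gene, 3 other filters on dim probes (detected on all 3 arrays, none, or the brighter signal above the array's median), and fold thresholds of 1.5 and 3. Chosen after seeing the data were the value table with columns matched by rank and the omission of probes with a G and T run. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 for normexp.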

Results

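Gene expression was measured in HoxA9-Meis1 AML cells, mouse acute myeloid leukaemia cells of C57Bl/6 origin that were isolated from bone marrow and are named for the homeobox transcription factors Hoxa9 and Meis1. The cells were left untreated, exposed to 3.4 µM of a compound named Pyrydopyrazine A2, or exposed to retinoic acid (RA) together with a vitamin D3 derivative (D3V), each at 10 µM. All cultures were sampled at 24 h. Per the labels, the aim was to compare the expression signature of each treatment with that of untreated cells. Each condition was measured on 1 one-colour Agilent array, so no comparison has a replicate check and no test across samples was possible. The differences below are values of single arrays.

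Of 59305 spots that were not controls, 27291 (46.0%) were well above background on the untreated array, 27739 (46.8%) on the array labelled RA plus D3V and 27634 (46.6%) on the array labelled A2. No spot was saturated. Replicate spots of one probe within an array had a median SD of 0.0703, 0.0674 and 0.0606 on the log2 scale on the untreated, RA plus D3V and A2 arrays (233, 229 and 233 probes with 10 spots each). The authors' deposited value table holds a second set of values for untreated cells that matched none of the scanner files. Between those values and the untreated scanner array the SD of the log2 difference was 0.284 over 17003 genes, and 159 of them (0.935%) lay at least 2-fold apart. These are the only spreads available. The origin of the second control values is unknown, so it is also unknown whether their difference from the array holds variation between cultures.

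The labels of the treated arrays are in doubt. The value table's column labelled RA plus D3V had the ranks of the scanner file labelled A2 (Spearman 1 over all spots), and its column labelled A2 had those of the scanner file labelled RA plus D3V (Spearman 1). The arrays are therefore called by the labels of their scanner files throughout, and every direction below is that of the array so labelled, not necessarily of the compound. Cyp24a1, Cyp26a1 and Tgm2, members of the retinoid and vitamin D response lists, were high on the array labelled A2 and in the value table's column labelled RA plus D3V.

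**Figure D1:**
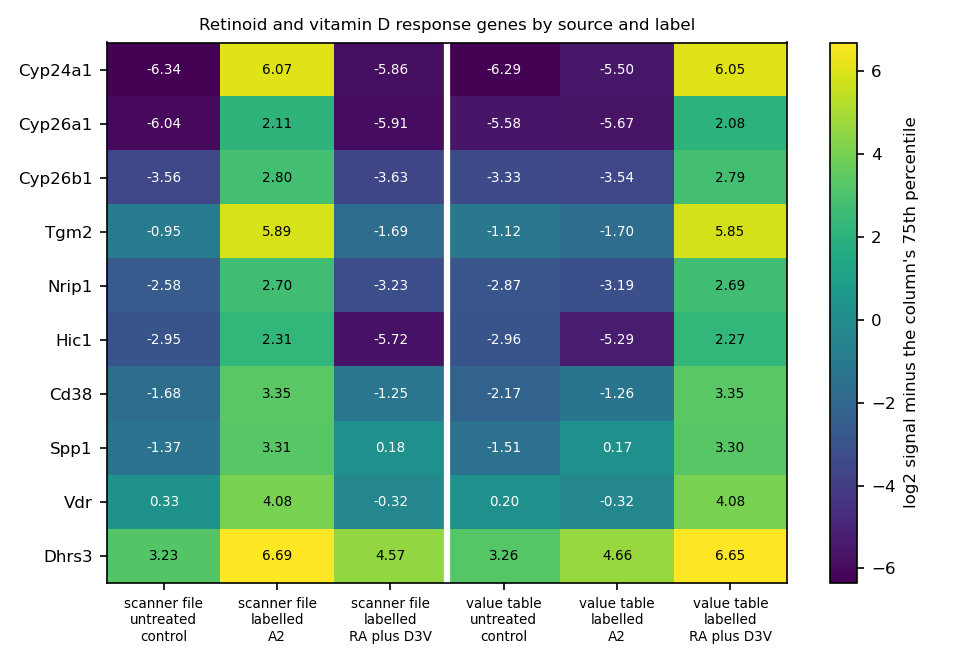
Log2 signal minus the column's 75th percentile for 10 genes of the retinoid and vitamin D response lists (vertical axis) on the 3 scanner arrays and in the 3 columns of the authors' deposited value table (horizontal axis). Cyp24a1 stood at 6.07 on the scanner array labelled A2 and at 6.05 in the value table's column labelled RA plus D3V, and lay below -5 in the other 4 columns.

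Several genes that retinoic acid or vitamin D are known to induce were far higher on the array labelled A2 than on the untreated array. Cyp24a1, the enzyme that degrades active vitamin D, was at least 1222-fold higher (probe at chromosome 2, 170308865 to 170308924, mm9), and Cyp26a1, a retinoic acid hydroxylase, was at least 78.7-fold higher (chromosome 19, 37775566 to 37775625). In the retinoid response list 6 of 11 measured members were at least 2-fold higher and 1, the receptor gene Rarg (-1.07), was at least 2-fold lower. The highest were the transglutaminase Tgm2 (log2 difference 6.83), the hydroxylase Cyp26b1 (6.35) and the nuclear receptor cofactor Nrip1 (5.27), followed by Hic1 (5.25), Cd38 (5.03) and the retinal reductase Dhrs3 (3.46). The list's median was 3.46, at the 100th percentile of 10000 random lists matched on signal. It rested on a list that was high in part: with members required above background on all 3 arrays it was 0.71. The retinoic acid receptor gene Rarb was not well above background on any array. Asb2 lay within 2-fold on the probe used (0.45). Its other probe, which these numbers leave out, was well above background on the array labelled A2 only, at a log2 signal of -0.02 against -6.16 on the untreated array. Among vitamin D response genes, the vitamin D receptor Vdr (3.76) and osteopontin, Spp1 (4.68), were higher, whereas the lipopolysaccharide co-receptor Cd14 (-1.24) was lower and the list's median of 0.20 lay at the 85.8th percentile.

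In total, 1369 of 17279 genes and transcripts measured on both arrays were at least 2-fold higher on the array labelled A2 and 1117 were at least 2-fold lower. For 12501 names in the RefSeq table the numbers were 1059 and 903. Of all genes and transcripts, 1077 of the 1369 higher and 902 of the 1117 lower ones kept a 2-fold difference in the same direction against the value table's control as well. With normexp the counts of genes and transcripts were 951 higher and 721 lower, and among genes with a brighter signal 925 and 646. The largest increases among brightly measured genes were the stress cytokine Gdf15 (8.65), the tight junction protein Cgn (7.83), the mitochondrial protein Mgarp (7.61), the chemokine Ccl6 (7.24), creatine kinase Ckb (7.02, with 7.07 on its second probe) and Tgm2. The others in the 12 were Mdfi (6.51), Cyp26b1, aldolase C, Aldoc (6.34), the microglial and macrophage receptor Trem2 (6.26), the kinase Dapk2 (6.24) and the secretory kinase Fam20c (6.08). Genes above background on the treated array only included arginase, Arg1 (at least 6086-fold), Cyp24a1 and the growth factor Tgfb3 (at least 181-fold).

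The largest decrease was that of lamin A/C, Lmna (-6.36, chromosome 3, 88287262 to 88287321). It was followed by Crip2 (-4.92), the 5'-nucleotidase Nt5e, also known as CD73 (-4.60), the lectin-like receptor Klrb1f (-3.90), Slc24a3 (-3.79), the chemokine Cxcl10 (-3.75), Cgref1 (-3.59), the urea cycle enzyme Ass1 (-3.56) and the caveolar protein Cavin1 (-3.53). The other 3 of the 12 were Rdh1 (-3.93), Med13 (-3.64) and Abca17 (-3.48). Each rests on a single bright probe that holds a run of at least 11 alternating G and T bases. Of 246 genes and transcripts measured by a probe with at least 8 such bases, 120 were at least 2-fold lower on both treated arrays, as described below. Genes above background on the untreated array only were led by the retinol carrier Rbp4 (at least 23.1-fold lower), Bex6 (at least 17.2-fold), the actin regulator Pfn2 (at least 14.6-fold) and the water channel Aqp3 (at least 14.3-fold).

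Among the myeloid lists, 14 of 23 measured monocyte and macrophage genes were at least 2-fold higher on the array labelled A2 and 2 were at least 2-fold lower (median 1.13, 100th percentile). Complement C1qb had a log2 difference of 2.04 and the Fc receptor Fcgr3 one of 1.73, whereas the fractalkine receptor Cx3cr1 was lower (-3.05). The receptor for colony stimulating factor 1, Csf1r, differed by 0.69. In the neutrophil maturation list 4 of 19 members were at least 2-fold higher and 1 lower (median 0.47, 99.8th percentile). The integrin Itgam, which encodes CD11b, was higher (2.37, with 2.13 and 2.35 on its other probes), as were Ly6g (1.90) and the integrin subunit Itgb2 (1.78), and the chemokine receptor Cxcr2 was lower (-2.54). Granule genes went both ways. Among 10 primary granule genes, myeloperoxidase, Mpo (-2.22), and Cst7 (-1.54) were lower and Ctsc (1.44) and Prss57 (2.83-fold) higher. Among 11 secondary and tertiary granule genes, the collagenase Mmp8 (5.02) and the gelatinase Mmp9 (3.73) were higher and the other 9 lay within 2-fold.

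All 16 measured genes of the glycolysis and hypoxia list were above their untreated level on the array labelled A2, 12 of them by at least 2-fold (median 1.64, 100th percentile). Ankrd37 (4.71), the mitophagy receptor Bnip3 (3.40), the oxygen sensor Egln3 (3.10) and the growth factor Vegfa (3.01) led the list. Of 19 cholesterol synthesis genes 7 were at least 2-fold higher and none lower (median 0.94, 100th percentile), with Sc5d (1.69), Mvd (1.39) and Lss (1.30) the highest. Ribosome biogenesis and Myc target genes were lower: 12 of 18 by at least 2-fold (median -1.11, 0th percentile), among them Rrp9 (-1.51), Nop58 (-1.48) and Polr1b (-1.41). The transcription factor Myc itself differed by -1.59. Of 15 nucleotide synthesis genes 5 were at least 2-fold lower, led by Gart (-1.96), Ctps (-1.39) and Cad (-1.31), and the list's median was -0.59 at the 0.14th percentile. Mitosis genes were lower as a group, with 7 of 25 at least 2-fold lower (median -0.83), among them Cdc20 (-1.42), Top2a (-1.39) and Prc1 (-1.29), while 23 of 24 DNA replication genes lay within 2-fold (median 0.08).

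Genes of the leukaemia program also shifted. Of 16 measured members of the HoxA9 and Meis1 list 6 were at least 2-fold lower and 2 higher on the array labelled A2 (median -0.45, 0.71th percentile). The receptor Flt3 (-2.28), Myc and the cyclin-dependent kinase Cdk6 (-1.43) were lowest. Hoxa9 was higher (1.19, with 1.82 on its second probe), as was the stem cell factor receptor Kit (1.70). Meis1 was not well above background on any array. It is read by a single probe, so Meis1 RNA without that stretch would not be seen. The anti-apoptotic gene Bcl2 differed by -1.09 on a probe with a G and T run of 8 bases. In the stem cell list the transcription factors Gfi1b (-3.29) and Gata2 (-2.99) were lower, and the other 6 measured members had a highest value of 1.11 (Egr1). The cell cycle inhibitor Cdkn1a differed by -1.05 on its brightest probe and by -0.73 and 0.24 on the others, and the median of 18 p53 targets was -0.26 (8.98th percentile) although Gdf15 belongs to that list.

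Of the other lists, apoptosis genes had a median of 0.46 (99.7th percentile; 4 of 17 at least 2-fold higher, led by Bmf at 1.68 and Bik at 1.48) and NRF2 targets one of 0.39 (99.2th percentile; 3 of 16 higher, with heme oxygenase, Hmox1, at 2.74). Interferon response genes had a median of 0.39 (99.5th percentile), with Zbp1 at 2.45 and Irf7 at 1.74 against Cxcl10 at -3.75. NF-kB and inflammatory genes split, with Ccl4 (4.78), Ccl2 (4.67) and Ccl3 (2.98) higher and Cd83 (-2.19), Tnf (-1.99) and Relb (-1.81) lower (median -0.10, 35.7th percentile). The integrated stress response list had a median of -0.50 (0.13th percentile), with Mthfd2 (-1.53) and Pck2 (2.82-fold) lower and Ddit4 (3.43) and Atf3 (2.15) higher. Medians inside the range of 95% of random lists were those of the aryl hydrocarbon receptor targets (0.46), ER chaperones (0.13), LXR targets (0.08), tubulins (-0.07), primary granule (0.10), secondary and tertiary granule (0.08), stem cell (0.10), DNA replication and heat shock (-0.24) lists. The reference genes, each read on its brightest probe, had a median of 0.07 and lay between -0.26 and 0.39. Gapdh differed by 0.245 on that probe and by 0.54 to 1.17 on its other probes.

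Markers of other cell types differed as well. T and NK cell genes were lower on the array labelled A2 (median -1.41, 0.01th percentile; 4 of 7 at least 2-fold lower), with granzyme A, Gzma, at -2.09, Cd3d at -1.86 and Cd2 at -1.81. Erythroid genes were below their untreated level in 7 of 7 measured members (median -0.75, 0.795th percentile), with Car2 at -1.73 and Hbb-b1 at -1.06. Platelet factor Pf4 (4.50) and Vwf (3.70) were higher and Itgb3 differed by -0.27, and these were the 3 of 10 megakaryocyte genes measured on both arrays. B cell (0.35), eosinophil, basophil and mast cell (-0.03), dendritic cell (-0.16) and stromal (0.63) medians lay inside the random range.

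The hydroxylases of retinoic acid and vitamin D were not detected on the array labelled RA plus D3V. Cyp24a1 and Cyp26a1 were not well above background on it or on the untreated array, Tgm2 differed by -0.74, Nrip1 by -0.65, Vdr by -0.64 and Cd38 by 0.43. Only Dhrs3 (1.35) was at least 2-fold higher among 10 measured retinoid response genes, whose median of 0.12 lay at the 70.0th percentile. With the stricter filter on dim probes that median was 0.58. The vitamin D response median was 0.11 (78.5th percentile), with Spp1 at 1.55 and Cd14 at -1.25. Over both lists, 10 of 29 members on the array design were at least 4-fold higher on the array labelled A2 and 0 on the array labelled RA plus D3V.

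Of 17279 genes and transcripts measured on both arrays, 1350 were at least 2-fold higher on the array labelled RA plus D3V than on the untreated array and 871 at least 2-fold lower. Among 12482 RefSeq names the numbers were 829 and 682. Of all genes and transcripts, 959 of the 1350 higher and 658 of the 871 lower ones kept a 2-fold difference against the value table's control. With normexp the counts of genes and transcripts were 745 higher and 531 lower, and among brighter genes 721 and 499. The leading increases were Mgarp (6.64), the chemokines Ccl7 (6.53), Ccl2 (5.71) and Ccl12 (5.53), the receptor ligand Gas6 (5.86), Aldoc (5.79), Pf4 (5.68), Cgn (5.62), Trem2 (5.32), Pigz (5.10), Ms4a7 (4.76) and the steroid side-chain cleavage enzyme Cyp11a1 (4.57). Genes above background on the treated array only were led by Fxyd4 (at least 110.1-fold), the mannose receptor Mrc1 (at least 90.5-fold), adenylate kinase Ak4 (at least 54.5-fold) and the platelet chemokine Ppbp (at least 40.95-fold, with a log2 difference of 4.37 from the value table's control).

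The largest decrease without a G and T run was that of the RNA helicase Ddx4 (-4.03, chromosome 13, 113388616 to 113388675). It was followed by Rbp4 (-2.80), the retinaldehyde dehydrogenase Aldh1a2 (-2.69), Cxcl10 (-2.63) and Cavin1 (-2.45). The remaining 7 of the 12 had such a run: Rdh1 (-3.79), Magef1 (-3.43), Med13 (-3.40), Golt1a (-3.37), Abca17 (-3.12), Blcap (-2.61) and Atp8a1 (-2.50). Genes above background on the untreated array only were led by Aqp3 (at least 12.4-fold lower), Pfn2 (at least 11.53-fold), Hoxa13 (at least 11.3-fold) and Eda (at least 10.2-fold). The values of Hoxa13 and Eda rest on the untreated scanner array alone, since the treated signals lay 1.47 above and 0.47 below the value table's control on the log2 scale.

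Mitosis genes were lower on the array labelled RA plus D3V in 25 of 25 measured members, 21 of them by at least 2-fold (median -1.30). Cdc20 (-1.89), Ccna2 (-1.70) and Kif23 (-1.69) were lowest, and none of 24 DNA replication genes differed by 2-fold (median 0.06). The p53 targets had a median of 0.79 (100th percentile; 6 of 18 at least 2-fold higher and 0 lower), led by Trp53inp1 (2.60), Gdf15 (2.44) and Btg2 (1.65). Cdkn1a differed by 0.81 on its brightest probe and by 2.35 and 2.68 on the others. Of 22 monocyte and macrophage genes 12 were at least 2-fold higher and 2 lower (median 1.17, 100th percentile), with C1qc (3.50), C1qb (3.02) and C1qa (2.98) highest and Cx3cr1 (-2.44) lowest. Itgam was higher (2.31) and Csf1r differed by 0.59. Neutrophil maturation genes had a median of 0.66 (100th percentile), with Cxcr2 2.82-fold higher, primary granule genes one of 0.39 (98.3th percentile), with Mpo at -1.57 and Prss57 at 1.45, and secondary and tertiary granule genes one of 0.40 (98.8th percentile), with Mmp8 at 4.01 and Mmp9 at 2.18.

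Glycolysis and hypoxia genes lay above their untreated level on this array as well, 16 of 16 and 8 by at least 2-fold (median 1.01, 100th percentile), with Ankrd37 (4.43), Egln3 (2.95) and Bnip3 (2.83) highest. Of 19 cholesterol synthesis genes 5 were at least 2-fold higher (median 0.72, 100th percentile), led by Fdps (1.36), Mvd (1.27) and Stard4 (1.22). The integrated stress response list was lower (median -0.57, at the 0th percentile; 6 of 19 at least 2-fold lower), led by Mthfd2 (-1.73), Pck2 (-1.44) and Asns (-1.37), with Ddit4 at 3.14. Ribosome biogenesis genes had a median of -0.56 with 1 of 18 at least 2-fold lower (Odc1, -1.07) and 1 higher, Cad (1.69), which is measured by a single probe. Myc differed by -0.64, Kit by 0.42 and Hoxa9 by 0.38 (-0.33 on its second probe), and the HoxA9 and Meis1 list had a median of 0.04 (72.1th percentile) although Flt3 was lower (-1.79).

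T and NK cell genes (median -0.88, 0.22th percentile) and erythroid genes (median -0.58, 2nd percentile) were also lower on the array labelled RA plus D3V, with Cd2 at -1.89 and Hbb-b1 2.15-fold lower, Pf4, Itgb3 (2.86) and Vwf (1.91), the 3 measured megakaryocyte genes of 10, were at least 2-fold higher, and stromal genes were higher (median 0.93 over 4 genes, 98.9th percentile), with Sparc 2.14-fold higher. Medians inside the random range were those of nucleotide synthesis (-0.25), interferon response (0.28), NRF2 targets (0.17), NF-kB and inflammatory (-0.11), apoptosis (0.21), aryl hydrocarbon receptor targets (0.26), LXR targets (-0.04), ER chaperones (0.13), heat shock (0.01), tubulins (-0.15), stem cell (0.20), B cell (0.08), eosinophil, basophil and mast cell (0.35), dendritic cell (0.08) and reference genes (0.05).

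**Figure D2:**
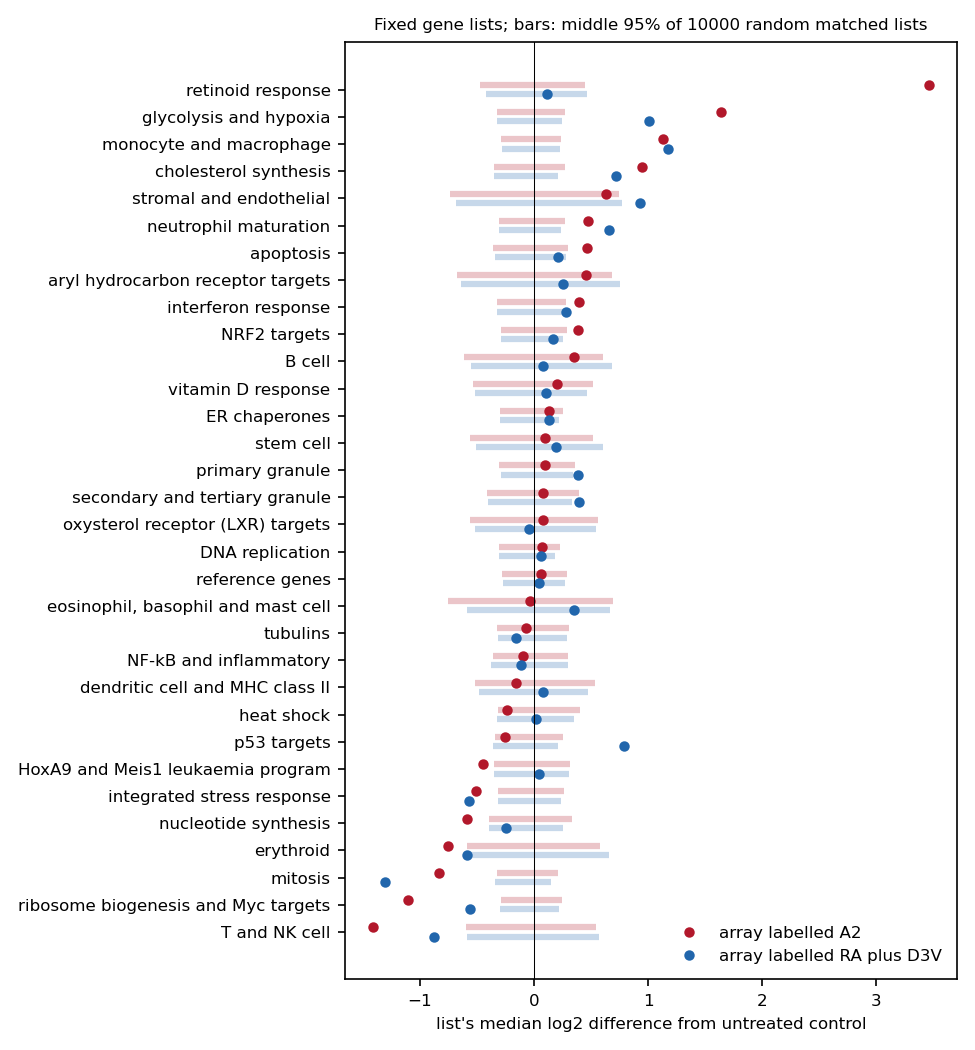
Median log2 difference from the untreated array over the measured members of each fixed list (points, red for the array labelled A2 and blue for the array labelled RA plus D3V; 1 array each), with the middle 95% of medians of 10000 random lists matched on signal (bars). Mitosis stood at -0.83 and -1.30, glycolysis and hypoxia at 1.64 and 1.01, and the retinoid response at 3.46 and 0.12.

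Set against each other, the treated arrays differed in retinoid response genes (median 0.43, 99.7th percentile), p53 targets, ribosome biogenesis genes (median -0.52, 0th percentile) and mitosis genes, among other lists. The retinoid median was 0.26 without a filter on dim probes and 1.36 with a stricter one. Among 17628 genes and transcripts measured on both, 665 were at least 2-fold higher on the array labelled A2 and 713 at least 2-fold higher on the array labelled RA plus D3V. That balance depends on dim probes and on scaling. The numbers were 488 and 333 with normexp background correction and 473 and 358 among brighter genes. With quantile normalization they were 681 and 660, and with median scaling 601 and 811. Arg1 (9.44), Tgm2 (7.57), Mdfi (7.50), the growth factors Hbegf (6.71) and Pdgfa (6.55), Gdf15 (6.20) and the kinase Camkk1 (6.03) were among the 8 highest on the array labelled A2. The 8 lowest there were Lmna (-5.66), Gas6 (-5.25), Mrc1 (-4.89), Klrb1f (-4.87), the calcium-binding protein S100a4 (-4.75), Slc24a3 (-4.73), Gpr162 (-4.67) and the fatty acid receptor Ffar2 (-4.53). Mitosis genes were higher on the array labelled A2 in 24 of 25 members (median 0.46, 100th percentile). The p53 targets were lower there, with a median of -0.66 and 8 of 19 at least 2-fold lower. Glycolysis and hypoxia genes had a median of 0.41 (100th percentile), with Vegfa (1.98) the highest.

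Over 17003 genes and transcripts measured on all 3 arrays, the log2 differences of the treated arrays from the untreated array correlated across genes, which are not independent replicates, with Pearson's r of 0.669 and Spearman's rho of 0.723. Both differences share the untreated array, and simulated arrays without any effect gave r of 0.499 through that alone. Equal noise on the arrays gives about that r at any noise level, so it does not measure how much of the observed r the shared array explains. The covariance was 0.395 against 0.0403 in that simulation. With the scanner control for one array and the value table's control for the other, r was 0.613 or 0.581 and the covariance 0.352 or 0.342. The origin of the value table's control is unknown, so both controls may still share variation of the untreated culture. At least 2-fold higher on both were 592 genes and transcripts, where independent lists would share 105.6, and at least 2-fold lower on both were 481, where independent lists would share 54.1. Part of either excess can come from the shared untreated array: with separate controls (scanner for the array labelled A2, value table for the other) the numbers were 504 and 437. In opposite directions went 43: 23 were higher on the array labelled A2 and lower on the other, and 20 the reverse.

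**Figure D3:**
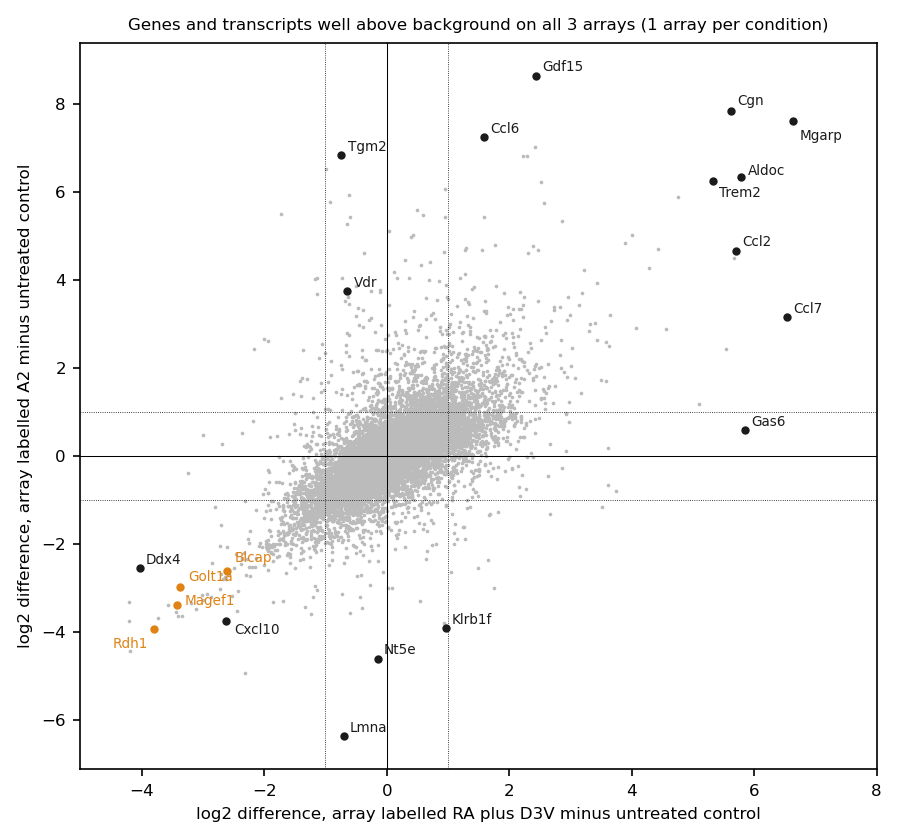
Log2 difference from the untreated array of each of 17003 genes and transcripts (points) on the array labelled RA plus D3V (horizontal axis) and on the array labelled A2 (vertical axis); dotted lines mark 2-fold. Mgarp, Cgn, Aldoc and Trem2 were high on both, Tgm2 (6.83 and -0.74) on the array labelled A2 only, and genes in orange have a probe with a run of alternating G and T bases.

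Many genes lower on both treated arrays were measured by probes of one kind. Of the 481 that were at least 2-fold lower on both, 120 (24.9%) were measured by a probe holding at least 8 alternating G and T bases in a row, although such probes made up 246 of the 17003 (1.45%), and of the 592 higher on both 1 had such a probe. Of 50 at least 4-fold lower on both, 30 had it. The probe of Golt1a (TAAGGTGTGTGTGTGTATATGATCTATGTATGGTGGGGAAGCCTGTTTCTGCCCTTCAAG, chromosome 1, 135219463 to 135219522, mm9), with log2 differences of -2.98 and -3.37, and that of Magef1 (chromosome 16, 21332081 to 21332140), with -3.38 and -3.43, are examples. On both probes the untreated array lay 0.83 above the value table's control on the log2 scale. The median gap was 0.05, 0.45, 0.44 and 0.245 over probes with 8 to 9, 10 to 12, 13 to 19 and at least 20 such bases. Over all probes with at least 8 it was 0.245. Against that control these decreases were therefore smaller, by little at 8 to 9 bases. In 34 genes with such a probe lower on both arrays and another measured probe without the run, the run probes had median log2 differences of -1.70 (array labelled A2) and -1.46 (array labelled RA plus D3V). The 45 other probes of the same genes had medians of 0.24 and 0.30, and 0 of them were at least 2-fold lower on both. Without these probes the numbers of genes at least 2-fold lower became 981 on the array labelled A2 and 742 on the array labelled RA plus D3V.

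**Figure D4:**
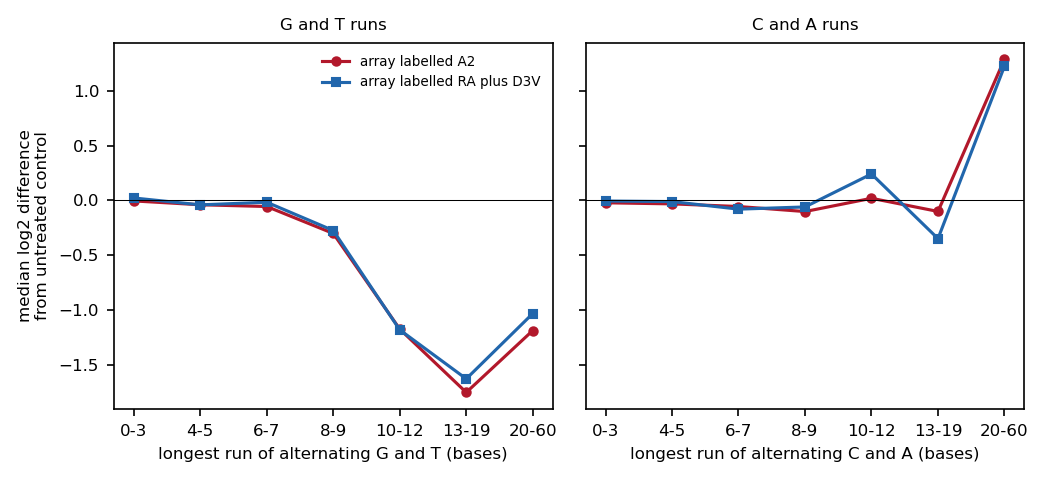
Median log2 difference from the untreated array (vertical axis) of probes grouped by their longest run of alternating G and T bases (left) or C and A bases (right), on the array labelled A2 (red) and the array labelled RA plus D3V (blue). Probes with 13 to 19 alternating G and T bases had medians of -1.75 and -1.63, and those with fewer than 8 lay within 0.1 of 0.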

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

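All tests weighed here were chosen after the results they bear on had been seen. The comparisons between treated and untreated arrays above do not rest on the treated columns of the authors' value table. Those columns had the ranks of the treated scanner arrays under exchanged labels, so they are not separate evidence of a response. The value table's column labelled RA plus D3V had a retinoid response median of 3.39 against its control column. Over spots well above background that column had a Pearson's r of 0.999774 with the scanner array labelled A2, the column labelled A2 had an r of 0.999944 with the scanner array labelled RA plus D3V, and the control column differed from the untreated scanner array with an SD of 0.287.

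The array labelled A2 carried the ligand response: 10 of 29 retinoid and vitamin D genes on the array design were at least 4-fold higher there and 0 on the array labelled RA plus D3V. A candidate explanation is that the scanner files of the treated arrays carry each other's label, since the value table's treated columns have the ranks of each other's file (Spearman 1). That A2 drives the response, the ligands do not and the scanner files' labels are right stays open: the 0 such genes on the array labelled RA plus D3V are part of the pattern itself and decide nothing. That the value table's control column is the untreated scanner file in another processing is argued against by a Spearman rho of 0.9356 over all spots. Genes that retinoic acid or vitamin D are known to induce were high in the data that the value table labels RA plus D3V. That favours the value table's labels without deciding the question. No biological explanation beyond the treatments was tested, and which of the sources has the right labels stays open without the authors' records.

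Probes with a run of alternating G and T were often lower on both treated arrays. The other probes of the same genes had a median log2 difference of 0.3043 on the array labelled RA plus D3V, and 0 of them were at least 2-fold lower on both arrays, which argues against lower levels of the named transcripts. Double-stranded DNA in the untreated sample is argued against by probes with a run of at least 10 alternating C and A bases, the other strand of the repeat, whose median was 0.30 on that array. These probes did not behave alike. At 10 to 12, 13 to 19 and at least 20 such bases the medians were 0.24, -0.35 and 1.225 there. On the array labelled A2 they were 0.02, -0.10 and 1.289. The cause of the rise at the longest runs was not tested. Labelled RNA with the complementary repeat that binds these probes whatever their gene may account for the decreases, a hypothesis found and tested on the same arrays. No source of such RNA in the cells was tested.

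Glycolysis and hypoxia genes lay above their untreated level on both treated arrays. An unusual untreated array as the whole cause is argued against by the value table's control, against which the lower of both medians was 1.03. Background correction as the cause is argued against by the median under normexp, 0.8622, the lowest over the other scalings and background correction. The other scalings moved the median of all genes too little to remove the rise, so they do not decide on scaling. The shifts were -0.016 and 0.034 (median scaling) and -0.023 and -0.022 (quantile normalization) on the arrays labelled A2 and RA plus D3V. Cultures that differed in oxygen or cell density and not through the treatments could give the same picture: the covariance of both differences remained 0.3524 with a separate control source for each, and with 1 culture per condition this cannot be told apart from an effect that the treatments share.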

How the results depend on the processing

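The value table with columns matched by rank and the omission of probes with a G and T run were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each condition has 1 array, and for the same reason no array could be left out in turn. A gene was taken as unmoved within 0.284 on the log2 scale, a list median within 0.102 and the correlation within 0.056, the spreads between the control sources, and a count within 1.5 times. Outside the value table with its columns as labelled, 815 of 988 values of named genes, 510 of 600 of list medians and 92 of 120 of counts were unmoved by these limits, and 0 of the called ones changed sign. These totals include values that could not move. Median scaling shifts all genes of a comparison by the same amount, here -0.016, 0.034 and -0.051, which is inside the limits for genes and list medians. The mean over a gene's probes leaves genes with a single probe as they are. Normexp gave most of the moved gene values: 115 of 198 moved under it. Median scaling, quantile normalization, the mean over a gene's probes and the omission of G and T run probes moved no count. Without a filter the median of all genes shifted by 0.21 on the array labelled RA plus D3V and by -0.16 between the treated arrays. Signal over background limits what can be seen, since 46.8% of the spots at most were well above it.

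With normexp, which adds an offset that shrinks dim values, 721 genes were at least 2-fold lower on the array labelled A2, and 745 were higher and 531 lower on the array labelled RA plus D3V. Between the treated arrays 488 were higher and 333 lower on the array labelled A2, so that 59.4% of the calls were higher against 48.3% in the values reported. Medians on the array labelled A2 were 3.29 (retinoid), 0.76 (monocyte) and 1.47 (glycolysis), and on the other 0.93 (monocyte) and 0.86 (glycolysis). With no filter, which counts probes at background level, the array labelled A2 had 3742 higher and 2647 lower, the other 4471 and 2039, and the comparison of both 1785 and 2940. The retinoid medians were 0.71 on the array labelled A2 and 0.26 between the treated arrays. With genes above background on all 3 arrays they were 0.71 and 0.60, as Cyp26b1 and Hic1 drop out, and the p53 median between the treated arrays was -0.82, as Plk2 drops out. With the brighter signal above the array's median, which tests fewer genes, 646 were lower on the array labelled A2, 721 higher and 499 lower on the other, and between both 473 were higher and 358 lower on the array labelled A2 (56.9% of the calls higher). Lists below the random range numbered 4 and 3, the retinoid medians were 4.24, 0.58 and 1.36, the p53 median between the treated arrays was -0.82 and Pearson's r was 0.741. At a fold of 1.5 the higher and lower counts were 2963 and 2943, 3050 and 2671, and 1564 and 1975; at 3 they were 592 and 336, 445 and 187, and 300 and 205.

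With the value table's columns matched by rank, the monocyte median on the array labelled RA plus D3V was 1.34 and the mitosis median -1.15; the cause was not tested. With its columns as labelled, the treated arrays exchange their ranks by construction. The column labelled A2 then had medians of 0.13 (retinoid), 1.34 (monocyte), 0.068 (HoxA9 and Meis1), -1.15 (mitosis), 1.03 (glycolysis) and -0.61 (ribosome biogenesis). The column labelled RA plus D3V had 3.39 (retinoid), -0.14 (primary granule), -0.78 (mitosis), -0.14 (p53) and 1.62 (glycolysis). Between them the medians were -0.47 (retinoid), -0.40 (mitosis), 0.73 (p53) and -0.33 (glycolysis). Genes reversed in the column labelled A2 were Bex6 (1.22), Cad (1.75), Cdk6 (0.0021), Cdkn1a (0.71), Cst7 (0.49), Cxcr2 (1.505), Cyp26b1 (-0.22), Gata2 (0.16), Gfi1b (0.40), Hic1 (-0.90), Klrb1f (1.00), Mdfi (-1.05), Nrip1 (-0.32), Rarg (0.27), Slc24a3 (0.95), Tgm2 (-0.58) and Vdr (-0.52). In the column labelled RA plus D3V they were Aldh1a2 (0.18), Cad (-0.98), Cxcr2 (-2.42) and Itgb3 (-0.26). Between the columns they were Arg1 (-9.49), Camkk1 (-6.04), Ffar2 (4.57), Gas6 (5.03), Gdf15 (-6.18), Gpr162 (4.43), Hbegf (-6.73), Klrb1f (4.83), Lmna (5.72), Mdfi (-7.49), Mrc1 (4.83), Pdgfa (-6.56), S100a4 (4.76), Slc24a3 (4.74), Tgm2 (-7.55) and Vegfa (-1.95).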

Other observations

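The array design holds 16171 probes for long intergenic noncoding RNAs, of which 3610 were well above background on the untreated array and the array labelled A2 together and 3640 on the untreated array and the array labelled RA plus D3V. On the array labelled RA plus D3V 412 of these (11.3%) were at least 2-fold higher than on the untreated array and 162 lower, against 224 higher and 205 lower on the array labelled A2. Over all measured genes and transcripts 7.8% and 7.9% were higher on these arrays. Increases on the array labelled RA plus D3V depend on dim probes, since normexp lowered their number over all genes from 1350 to 745. Whether this holds for the noncoding probes was not tested. A transcribed region on the reverse strand of chromosome 8 (82836971 to 82849309, mm9) was higher on the array labelled A2 by 6.03 and 5.44 on 2 probes on the log2 scale, and by 0.58 and 0.95 on the array labelled RA plus D3V. A region on the reverse strand of chromosome 19 (5798135 to 5800557) was higher on the array labelled RA plus D3V by 3.63, 3.53 and 3.39 on 3 probes, and on the array labelled A2 by 2.51, 2.32 and 2.24. These regions were chosen after their values were seen.

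Between the treated arrays, 7 of 33 lists had a median above the range of 95% of random lists and 9 below it. Interferon response genes were higher on the array labelled A2 (median 0.34), led by Zbp1 (1.66) and Gbp2 (1.38), and so were NRF2 targets (0.29), led by Osgin1 (2.05), and the integrated stress response list (0.30). Ribosome biogenesis genes were lower there (median -0.52), as were nucleotide synthesis (-0.35), dendritic cell and MHC class II (-0.48, with Cd74 at -1.95), secondary and tertiary granule (-0.28) and monocyte and macrophage genes (-0.19, with C1qa at -2.21 and Klf4 at -3.02). The granule median stands beside a value of 9.44 for its member Arg1.

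Values differed along transcripts. This was seen in 740 genes with measured probes at both ends of a span of 10000 to 1000000 bases of the genome, introns included. The probe nearest the 5' end lay above the probe nearest the 3' end in its difference from the untreated array. The median gap was 0.34 on the array labelled RA plus D3V and 0.16 on the array labelled A2, or 0.24 and 0.099 after a trend with signal was removed. For probes less than 1000 bases apart the medians were 0.0041 and -0.0044 (1041 genes). Both treated arrays are set against the same untreated array, and how far this shift enters the gene counts and the correlation was not tested. In 8 of 4522 genes with several measured probes on the untreated array and the array labelled A2, probes lay at least 2-fold from the untreated array in opposite directions, and in 10 of 4525 on the array labelled RA plus D3V. In 581 and 666 of these genes some probes passed 2-fold and others did not.

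Of the values over 1000 in the value table's control column, 89.5% had at most 3 decimals after multiplication by 8 and 15.7% after multiplication by 3. The median of each column was 17.4.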
